A study of Mus musculus with 52 samples.

How the data were processed

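Bone marrow RNA of 47 female mice was measured on Illumina mouseWG-6 v2.0 bead arrays, 1 array per mouse, together with 5 arrays of a reference RNA that the labels do not describe further. Per the labels, the mice were MMTV-NeuT transgenic (NeuT+) or non-transgenic siblings (NeuT-) killed at 6, 12 or 24 weeks. RNA was extracted with Trizol and had an integrity number above 7, per the series' design text. The design text names a TotalPrep amplification kit while the labels' protocol field names the whole genome DASL assay, and the sources used here do not settle which was run.

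The deposited raw values gave the intensity of each of 45281 probes on each array on a linear scale, as exported from BeadStudio 3.3.8 per the series' design text. A detection p-value stood beside each intensity in the deposited raw table and sets the probe against the array's background. The authors' processed values were log2 intensities after robust spline normalization with lumi, per the series' design text and the submitters' processing notes, and the lumi version is not given in the sources used here. The design text describes a filter on detection that the deposited log2 values did not carry, since all 45281 probes were present. Their medians lay between 6.90 and 6.93, and each of the 52 deposited columns correlated best with the raw column of its own array, with a Spearman correlation of 1. Scale and columns of the deposited log2 values are therefore settled. No sample column was left without a matching sample.

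Probes were named from the platform's annotation table: 34885 probes had 1 gene symbol, 18 had several and 10378 were not listed and are unnamed here. Symbols were brought up to date with a RefSeq table of the assembly GRCm38.p6, used for names and for the order of genes only. Of the named probes, 34807 matched by Entrez number and 11 by accession, 67 kept the annotation's symbol, and 10 symbols changed. No gene was named from a probe with several symbols.

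Raw intensities were background corrected and quantile normalized with limma's neqc, which estimated the background from the detection p-values and added an offset of 16. Probes with a detection p under 0.01 on at least 1 of the 52 arrays were kept, 21592 in all, of which 18225 had 1 symbol. Each gene was represented by its probe with the highest mean over the mouse arrays, which gave 11309 genes. For called genes named in the genotype comparisons, all other detected probes of the same gene had the same sign, though not always a like size. Probes of near-identical gene copies can bind each other's RNA, and values of Bglap and Bglap2, of the Klk1 family, of the histone gene H2ac8 and of Oas1a are uncertain for that reason.

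Genes were tested on the log2 scale with limma's lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The animal number in each sample title falls into 6 number series by its leading digits (11, 12, 13, 14, 15 and 17), and the labels do not say what a series stands for. Genotypes were compared within each age in a fit of all mice with the number series within age as a fixed block, 8 blocks in all. Differences of the genotype effect between ages came from the same fit. Ages were compared within each genotype in a fit of the 6 groups without a block, because series 12 was the only one that held more than 1 age. Standard errors are those of the moderated fit, and each mouse is a separate animal per the labels. The design, the gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined.

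Where a probe was detected on no array of a group, the fold is given only as a bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the array's lowest detected signal and the probe's own signal. No fold is given where that bound was under 1 or where both groups were below background.

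In all, 25 gene lists were tested with limma's camera, which asks whether a list's genes shift against all other genes, with a preset correlation between genes of 0.01, and again with an estimated correlation. Limma's fry was run beside it; its p-value tests whether a list's genes move on balance one way and does not compare them with other genes. Adjusted p-values of lists are over the 25 lists of a comparison. Counts of members are given over all genes tested and also adjusted over the list alone. The lists were promyelocyte primary granule, neutrophil secondary granule and maturation, monocyte, resident macrophage, dendritic and plasmacytoid dendritic cell, MHC class II presentation, B-cell development, plasma cell, T and NK cell, erythroid, megakaryocyte and platelet, stem and progenitor cell, eosinophil, basophil and mast cell, mesenchymal stroma and extracellular matrix, osteoblast and osteocyte, osteoclast, endothelial, adipocyte, cell cycle, interferon response, inflammatory cytokine and NF-kB, myeloid suppressor function, immediate early and heat shock, skeletal muscle, and mammary epithelium. The myeloid suppressor list shares 4 of its 21 genes with other lists, the neutrophil list 3 of 22, and the osteoclast, inflammatory, dendritic cell, stem cell, endothelial and adipocyte lists 1 each. The mammary, skeletal muscle and osteoblast lists share 0 genes with any other list. A list's score in a mouse is the mean over its measured genes of the log2 value centred on each gene's mean.

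The text names, for each genotype comparison, Erbb2 and the 10 highest and 10 lowest log2 fold changes among genes past the threshold, or all where fewer passed. For each age comparison and each difference between ages it names the 5 highest and 5 lowest, and where none passed, the 5 with the smallest p. Up to 4 members with the smallest p are named per list. In addition, 15 genes were named after their values were seen: Clec9a, Klk1b5, Nfkbid, Sox13 and Fam189a1 at 6 weeks, Cd160, Zg16, Klk1, Klk1b26 and Klk1b27 across ages, and Dct, Mlana, Krt8, Mpo and S100a9 on the reference arrays.

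Log10 of tumor burden, given in the labels without a unit, was set against each list score over the 6 NeuT+ mice with a burden above 0 at 12 weeks and the 6 at 24 weeks, with exact permutation tests and adjustment over 25 lists. Other settings tried were the deposited log2 values, log2 quantile normalization without background correction, median scaling, no detection filter, detection on at least 5 arrays, the mean of a gene's probes, eBayes with trend and robust settings, a fit of the compared groups alone, no block, a random block, series 12 alone, and leaving out each 24-week mouse. Further alternatives were chosen after seeing the data: median raw signal, the osteoblast score or the immediate early score as covariate, leaving out series 17, 24-week mice of series 13 alone, and leaving out each younger mouse.

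The steps were tested on simulated data in which 200 of the 11309 genes of each genotype comparison were changed. Recovery at a 1.5-fold and a 2-fold change was 84% and 100% for the 6-week comparison, 81% and 98% for the 12-week comparison and 76% and 90% for the 24-week comparison. In the same simulations 16 of 200 calls at 6 weeks, 9 of 188 at 12 weeks and 5 of 171 at 24 weeks were false. The noise was drawn independently for each gene, so correlation between genes was absent. With 200 changed genes the adjusted threshold is also easier to pass than with few. These rates are therefore no estimate of power in the real comparisons, of which that at 6 weeks called 1 gene. Depth on arrays has no read count, and the number of arrays limits the precision. R 4.3.3, limma 3.58.1 and version 1.17.8 of the data.table package were used, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for the plots.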

Results

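Bone marrow of female BALB/c mice was profiled by bead array in a model of spontaneous mammary carcinogenesis. MMTV-NeuT mice carry an activated rat Erbb2 oncogene driven by a mammary tumor virus promoter and develop mammary tumors with age. There were 9 NeuT+ and 9 NeuT- mice at 6 weeks, 9 and 9 at 12 weeks, and 6 NeuT+ and 5 NeuT- mice at 24 weeks. A further 5 arrays held reference RNA. Each array carried 45281 probes, of which between 14578 and 17057 were detected (median 15770.5), and median raw signals ran from 100.4 to 162.3. NeuT+ mice at 24 weeks had 15001.3 ± 426.4 detected probes (SD, n = 6) against 15580.8 ± 685.8 in NeuT- mice of that age (SD, n = 5). Their arrays also lay farther from the typical profile: the median interquartile range of relative log expression was 0.517, against 0.265 to 0.305 in the other mouse groups. No pair of arrays held identical values, and the highest correlation, 0.997, was between reference arrays 4 and 5. Each mouse was a separate animal, so p-values of single genes measure the spread between animals, and the number of arrays limits the precision. Camera's p-values with the preset correlation set a list's genes against all other genes and do not measure that spread.

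At 6 weeks, when 3 of the 6 NeuT+ mice with a recorded tumor burden had one above 0, the comparison of genotypes asked whether the marrow already differed. Peg3, an imprinted gene expressed from the paternal copy that encodes a zinc finger protein, was 64.8-fold higher in NeuT+ mice (log2 fold change 6.02 ± 0.152 SE, n = 9 and 9, limma adjusted p = 9.55e-30), with 2 of 9 NeuT- mice detected. The lowest NeuT+ mouse lay above the highest NeuT- mouse. Peg3 was also 79.6-fold higher at 12 weeks (log2 fold change 6.31 ± 0.154 SE, n = 9 and 9, adjusted p = 2.10e-30), with 1 of 9 NeuT- mice detected. Both folds are therefore set against signals near background. Peg3 was at least 17.4-fold higher at 24 weeks (n = 6 and 5, adjusted p = 5.79e-21), an age at which 0 of 5 NeuT- mice had a detected signal. Raw Peg3 signals ran from 729.4 to 5885.8 in the 24 NeuT+ mice and from 119.7 to 199.6 in the 23 NeuT- mice, without overlap. Within number series the Peg3 difference was 6.08, 6.38 and 5.59 log2 units at 6 weeks in series 12, 14 and 17. It was 5.84, 6.20 and 6.75 at 12 weeks in series 11, 12 and 15. Some of these series held no detected NeuT- mouse, so these differences are set against background and are not measured folds. At 24 weeks the NeuT+ mean was a log2 level of 10.42 ± 0.881 (SD, n = 6) against 12.13 ± 0.263 at 12 weeks (SD, n = 9). In series 12 the NeuT+ mean was 11.53 at 24 weeks (n = 2) and 11.96 at 12 weeks (n = 3). It was 9.87 in series 13 (n = 4), which held 24-week mice alone, so the lower mean cannot be told apart from series. A second Peg3 probe showed the same contrast at lower signal, with raw means of 863.0, 954.6 and 381.9 in NeuT+ mice at the 3 ages. A probe of still lower signal was detected in 4 of 9, 3 of 9 and 0 of 6 of them. Another Peg3 probe was detected on no array. The array's probe for Erbb2, which is designed on the mouse gene, was below background in all 47 mice, so no fold is given at any age and it does not check the transgene.

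**Figure D1:**
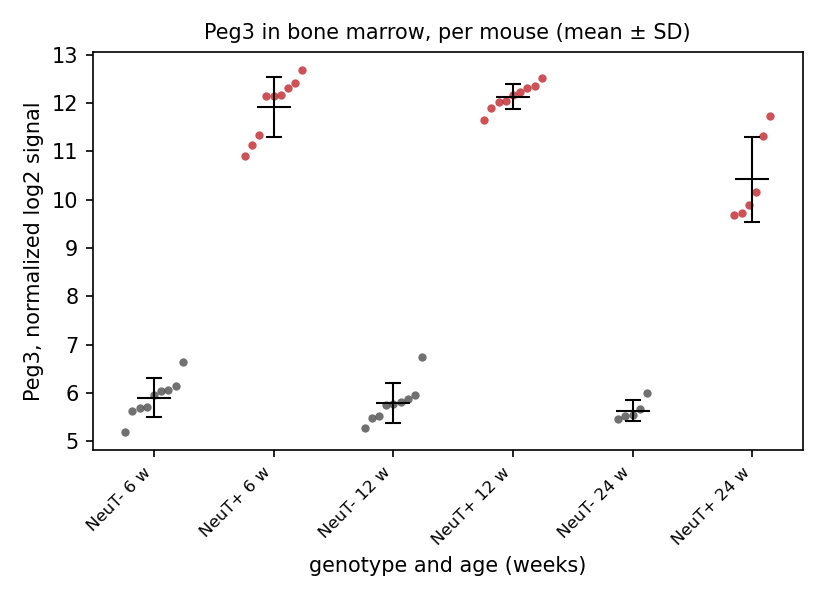
Normalized log2 signal of Peg3 in each mouse (points) for NeuT- and NeuT+ mice at 6, 12 and 24 weeks, with group mean and SD as bars. The NeuT+ means were 11.92, 12.13 and 10.42 and the NeuT- means 5.90, 5.80 and 5.64, and no NeuT+ point lies among the NeuT- points.

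Peg3 was the single gene of 11309 past adjusted p 0.05 at 6 weeks, while 716 had an unadjusted p under 0.05. Among those with the next smallest p, chosen after their values were seen, Clec9a, a receptor of cross-presenting dendritic cells, had a log2 fold change of -0.52 ± 0.106 (SE, n = 9 and 9, adjusted p = 0.103) and was detected in 1 of 9 NeuT+ and 8 of 9 NeuT- mice. Klk1b5, a kallikrein gene, stood at -0.66 ± 0.141. Nfkbid, an inhibitor-type regulator of NF-kB, stood at 0.41 ± 0.0897. Sox13 stood at 0.43 ± 0.0979 (adjusted p = 0.162), and Fam189a1 was detected in 1 of 9 NeuT+ and 0 of 9 NeuT- mice. Camera called 6 of the 25 lists, 5 higher and 1 lower, although 0 of their members passed over all genes (limma) and fry called 0 lists. B-cell development genes had a median log2 change of 0.25 (0 of 16 passing, and 0 adjusted over the list alone; adjusted p = 9.67e-05, and adjusted p = 0.583 with an estimated correlation). Ebf1 stood at 0.36, Rag1 at 0.57 and Ms4a1 at 0.37. The osteoblast list had a median of 0.40 (0 of 7 passing, 1 higher adjusted over the list alone; adjusted p = 0.000916, and adjusted p = 0.321 with an estimated correlation). Sp7, a transcription factor of bone formation, was detected in 4 of 9 NeuT+ and 0 of 9 NeuT- mice. Inflammatory genes had a median of 0.18 (0 of 20, and 0 adjusted over the list alone; adjusted p = 0.00135). Cxcl2 stood at 0.68. Immediate early genes also had a median of 0.18 (0 of 18, and 3 higher adjusted over the list alone; adjusted p = 0.00331). Egr1 stood at 0.57. Both had an adjusted p = 0.547 with an estimated correlation. Skeletal muscle genes had a median of 0.13 (0 of 7, and 1 higher adjusted over the list alone; adjusted p = 0.0171, and adjusted p = 0.547 with an estimated correlation). That median turned to -0.081 without the mice of series 17. Cell cycle genes had a median of -0.06 (0 of 24, and 0 adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.583 with an estimated correlation). Top2a stood at -0.12. Within series 12, 14 and 17 the genotype difference of the score was 0.26, 0.03 and 0.49 for B-cell development, 0.13, 0.51 and 0.61 for osteoblasts and 0.43, 0.03 and 0.05 for inflammatory genes. The number of genes was 2 without NeuT- replicate 4, NeuT- replicate 6 or NeuT+ replicate 8. It was also 2 with a random block and with the osteoblast score as covariate. The number of lists ran from 4 without NeuT- replicate 7 to 10 without NeuT+ replicate 1. The cell cycle list was lost without NeuT- replicate 2, 4 or 7 or NeuT+ replicate 8 (adjusted p from 0.0560 to 0.170), without series 17, with the immediate early score and with median scaling (over all alternatives 0.000858 to 0.583). The immediate early list was lost without NeuT- replicate 1 (0.0620) and without a block (over all, its own score as covariate included, 0.000124 to 0.547). For the inflammatory list this happened with the immediate early score (0.0507; over all 8.49e-05 to 0.547), and for the muscle list without NeuT- replicate 4, 7 or 8 or NeuT+ replicate 7 or 8 (0.0510 to 0.129; over all 0.00127 to 0.861). Medians were 0.15 for B-cell genes without series 17, 0.26 for osteoblast genes without NeuT+ replicate 9, 0.10 for inflammatory genes without NeuT- replicate 1, and 0.05 and 0.20 for muscle genes without NeuT- replicates 4 and 5. With the deposited and the log2 quantile values the osteoblast median was 0.21 and 0.20.

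At 12 weeks, 14 genes were higher and 3 lower in the marrow of NeuT+ mice. Trem1, a receptor that amplifies inflammatory responses of myeloid cells, was 2.12-fold higher (log2 fold change 1.08 ± 0.239 SE, n = 9 and 9, limma adjusted p = 0.0397). Tnfaip3, an enzyme that limits NF-kB signalling, was 2.08-fold higher (1.05 ± 0.236 SE, adjusted p = 0.0454), and Dusp5, a phosphatase that inactivates ERK kinases, was 2.11-fold higher (1.08 ± 0.209 SE, adjusted p = 0.0153). Ddit3, a transcription factor of the unfolded protein response, rose 1.71-fold (0.78 ± 0.142 SE, adjusted p = 0.00981). Nfkbib, an inhibitor of NF-kB, rose by 0.60 ± 0.124 log2 units. Bbc3, which promotes apoptosis, rose by 0.64 ± 0.134 on its brightest probe but stood at 0.048 on its other detected probe, and its call was lost on the mean of its probes. The transcription factor gene Ets2 rose by 0.57 ± 0.126 and Cd160, a receptor of NK and T cells, by 0.50 ± 0.0986. Apold1 also passed (adjusted p = 0.00981) but was detected in only 2 of 9 NeuT+ and 0 of 9 NeuT- mice, so no fold is given. The 3 genes lower in NeuT+ were the histone gene H2ac8 (-0.74 ± 0.154), Qprt, an enzyme of NAD synthesis (-0.34 ± 0.0781), and Dph2, an enzyme of diphthamide synthesis (-0.31 ± 0.0674). Values of NeuT+ and NeuT- mice overlapped for each of these genes named at 12 weeks other than Peg3. In all 17 genes passed, and 985 had an unadjusted p under 0.05. With median scaling 20 passed and 95% of them were higher, against 82.4% here.

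Inflammatory cytokine and NF-kB genes were shifted upward at 12 weeks, with a median log2 change of 0.28 over 20 measured members (camera adjusted p = 3.42e-10, and adjusted p = 0.0442 with an estimated correlation; fry adjusted p = 0.0191). Of them 1 was higher over all genes tested, Tnfaip3, and 9 were higher adjusted over the list alone. The chemokine gene Ccl4 stood at 0.91 ± 0.232 and Il1r2, a decoy receptor of interleukin-1, at 0.68 ± 0.176, without passing over all genes, and Cxcl1 was detected in 2 of 9 NeuT+ and 0 of 9 NeuT- mice. The score difference of this list was 0.54, 0.26 and 0.30 within series 11, 12 and 15, and that of Trem1 1.54, 0.93 and 0.90. Immediate early genes had a median of 0.21 (0 of 18 passing, 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.00456, and adjusted p = 0.933 with an estimated correlation). Atf3 stood at 1.58 ± 0.401 and Ier2 at -0.99, and their score differed by 0.34, 0.22 and 0.01 within those series. Myeloid suppressor genes had a median of 0.06 (0 of 17, and 0 adjusted over the list alone; adjusted p = 0.0462, and adjusted p = 0.933 with an estimated correlation). Stat3 stood at 0.31 and Clec4e at 0.36. The number of genes was 2 without NeuT- replicate 1, 32 and 41 without NeuT- replicates 2 and 6, and 9, 5 and 8 without NeuT- replicates 4, 8 and 9. It was 8, 11, 7, 10, 6 and 5 without NeuT+ replicates 2, 3, 4, 5, 7 and 8. Without a block 2 genes passed, with the deposited values 32, with log2 quantile values 31, with the mean of probes 33 and with the compared groups alone 26. The osteoblast and immediate early scores as covariates left 10 and 5. Of 31 alternatives, Trem1 was lost in 17, Tnfaip3 and Ets2 in 18, Qprt in 25, Dph2 in 14, Bbc3 and H2ac8 in 11, Nfkbib in 10 and Cd160 in 5. Dusp5 and Ddit3 were lost in 2, without a block and without NeuT- replicate 1. Apold1 was lost in 2 of 30 and Peg3 in 0 of 31. The myeloid suppressor list was lost without NeuT- replicate 2, 4, 7 or 9 or NeuT+ replicate 2, 3, 5 or 7 (adjusted p from 0.0736 to 0.325). It was also lost, like the immediate early list, without a block and with the osteoblast score as covariate. The immediate early score as covariate ended both calls, but is the second list's own score and says nothing of that list (adjusted p over all alternatives 0.0120 to 0.933 and 0.000132 to 0.933).

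At 24 weeks, when all 6 NeuT+ mice carried tumors, the marrow differed widely between genotypes, with lower expression of B-cell, plasma cell and erythroid genes and higher expression of genes of macrophages, neutrophils and the interferon response by camera's preset correlation. With an estimated correlation the plasma cell list alone was called among these 6 (adjusted p = 0.0281, against 0.0751 for B-cell development and 0.234 for the others), and the macrophage score difference was -0.64 within series 12 and 0.96 within series 13. Of 11309 genes, 1954 passed (17.3%), 788 higher and 1166 lower in NeuT+, and 35 and 121 of these differed by more than 2-fold. Prok2, which encodes the chemokine-like prokineticin 2, was 3.25-fold higher (log2 fold change 1.70 ± 0.405 SE, n = 6 and 5, limma adjusted p = 0.00346). Acod1, the itaconate-producing enzyme of activated macrophages, was 3.06-fold higher (1.61 ± 0.280, adjusted p = 0.000115), and the adhesion molecule gene Mcam 3.08-fold higher (1.62 ± 0.326, adjusted p = 0.000666). Upp1, a uridine phosphorylase, rose by 1.44 ± 0.255 log2 units, Vsig4, a complement receptor of macrophages, by 1.42 ± 0.323 and Wfdc17 by 1.36 ± 0.383. The transglutaminase gene Tgm1 rose by 1.35 ± 0.298, Ambp by 1.34 ± 0.342, and Oas3, an antiviral synthetase induced by interferon, by 1.33 ± 0.262. Vsig4 was detected in 5 of 6 NeuT+ and 1 of 5 NeuT- mice, and Ambp in 5 of 6 and 2 of 5.

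The lowest fold changes at 24 weeks were those of Bglap, Bglap2 and Col1a1, while the osteoblast and stroma lists were not called (adjusted p = 0.159 and adjusted p = 0.108). Bglap, which encodes osteocalcin, was 4.69-fold lower in NeuT+ (log2 fold change -2.23 ± 0.529 SE, n = 6 and 5, adjusted p = 0.00339), and its near copy Bglap2 4.61-fold lower (-2.20 ± 0.527, adjusted p = 0.0036). Col1a1, a chain of type I collagen, was 4.52-fold lower (-2.18 ± 0.560, adjusted p = 0.00641). Bglap was detected in 2 of 6 NeuT+ and 5 of 5 NeuT- mice, and Col1a1 in 1 of 6 NeuT+ mice. Fcmr, the Fc receptor for IgM, fell by 1.80 ± 0.287 and Cd72, a co-receptor of B cells, by 1.71 ± 0.273. Chst3, a chondroitin sulfotransferase, fell by 1.86 ± 0.288 and the kinase gene Srpk3 by 1.85 ± 0.299. Reln, which encodes the secreted glycoprotein reelin, fell by 1.85 ± 0.302, Myzap by 1.73 ± 0.257, and 4930426D05Rik by 2.03 ± 0.299. Values of the NeuT+ and NeuT- mice did not overlap for Peg3, Upp1, Oas3, Reln and Myzap. The calls of Bglap, Bglap2 and Col1a1, and of Wfdc17 and Ambp, were lost without NeuT- replicate 1, with series 13 alone and with the osteoblast score as covariate. Bglap and Bglap2 are members of the osteoblast list, so that score takes up part of their own change. In the other alternatives Bglap ran from -2.62 to -1.36. All of these but Bglap, and also Mcam, Vsig4, Tgm1, Prok2, 4930426D05Rik, Chst3, Srpk3, Fcmr and Cd72, were lost in a fit of the compared groups alone, and Prok2 also without NeuT- replicate 1. Of 47 mice 6 correlated most closely with the mean of a group of another age. NeuT- replicate 1 had the widest gap among them (0.994 with the 12-week NeuT- mean, 0.984 with its own group), and its age label is uncertain for that reason. The count of 1954 was 341 without NeuT- replicate 1 (323 of them among the 1954) and 1190 without NeuT+ replicate 2. It was 431 with series 13 alone (129 higher and 302 lower, 411 shared), 278 in a fit of the compared groups alone, 1259 without a block and 1160 with the osteoblast score. With median scaling 21.0% of 1532 calls were higher, against 40.3% here.

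The B-cell development, plasma cell, MHC class II, dendritic cell and T and NK cell lists were called lower in NeuT+ marrow at 24 weeks, and the plasma cell list alone among them was called with an estimated correlation. Of 16 measured B-cell development genes 14 fell and 2 did not pass (15 lower adjusted over the list alone), with a median log2 change of -1.28 (camera adjusted p = 8.41e-15, and adjusted p = 0.0751 with an estimated correlation). Cd79b, a signalling chain of the B-cell receptor, fell by 1.57 ± 0.238, Fcrla by 1.60 ± 0.243 and the kinase gene Blk by 1.57 ± 0.251. Of 9 plasma cell genes 6 were lower in NeuT+ (6 lower and 1 higher adjusted over the list alone, median -0.76, camera adjusted p = 0.00165). This was the one list of this age whose call held with an estimated correlation (adjusted p = 0.0281). The plasma cell score was -0.03 in NeuT- and -0.02 in NeuT+ mice at 12 weeks, and 0.56 and 0.02 at 24 weeks. By group means the difference thus came with a higher score in older NeuT- mice. In series 12, which alone held both ages, the NeuT+ score was 0.06 at 12 weeks (n = 3) and -0.15 at 24 weeks (n = 2). The NeuT- score there was 0.06 (n = 3) and 0.59 (n = 1). In series 13, which held 24-week mice alone, the NeuT+ score was 0.10 (n = 4), so a fall in NeuT+ is not excluded. Jchain, which joins secreted antibody chains, was lower by 1.13 ± 0.180, Mzb1 by 1.06 ± 0.161 and the transcription factor gene Irf4 by 1.18 ± 0.258. Of 10 genes of MHC class II presentation 7 fell (10 lower adjusted over the list alone; median -0.52, adjusted p = 1.83e-06, and adjusted p = 0.128 with an estimated correlation). H2-Ob fell by 1.67 ± 0.256 and Ciita, the transactivator of these genes, by 0.94 ± 0.166. Of 9 dendritic cell genes 6 fell (6 adjusted over the list alone; median -0.61, adjusted p = 0.000837, and adjusted p = 0.0751 with an estimated correlation). Klk1 stood at -1.37 ± 0.222, Siglech, a surface marker of plasmacytoid dendritic cells, at -0.61 ± 0.157 and Batf3 at least 1.21-fold lower. Of 11 T and NK cell genes 5 fell (6 lower and 1 higher adjusted over the list alone; median -0.32, adjusted p = 0.0307, and adjusted p = 0.305 with an estimated correlation). Cd2 stood at -1.11 ± 0.212 and Klrd1 at -0.75 ± 0.147. Series 12 held 2 NeuT+ mice and 1 NeuT- mouse of this age and series 13 held 4 and 4. Score differences within them were -2.43 and -0.85 for B-cell development, -0.73 and -0.45 for plasma cells and -1.19 and -0.46 for MHC class II. Without NeuT- replicate 1 the MHC class II median was -0.32. The T and NK cell list was lost without this mouse (median -0.20, adjusted p = 0.128), without NeuT+ replicate 2 (0.0505) or replicate 6 (0.0864), with series 13 alone and with the osteoblast score as covariate (adjusted p over all alternatives 0.0120 to 0.305). With the deposited and the log2 quantile values the medians were -0.37 and -0.33 for dendritic cell genes, -0.36 and -0.33 for plasma cell genes and -0.16 in both for T and NK cell genes.

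In the lists called by camera, erythroid genes were lower and macrophage, neutrophil, promyelocyte and myeloid suppressor genes higher, and each of these calls was lost with an estimated correlation. Of 22 erythroid genes 17 fell in NeuT+ (20 adjusted over the list alone), with a median log2 change of -0.77 (adjusted p = 1.73e-09, and adjusted p = 0.234 with an estimated correlation). Slc4a1, the anion exchanger of the red cell membrane, fell by 1.04 ± 0.278, Car1, an erythroid carbonic anhydrase, by 0.85 ± 0.203, and Urod, an enzyme of heme synthesis, by 0.47 ± 0.111. Of 12 resident macrophage genes 5 were higher in NeuT+ (5 adjusted over the list alone, median 0.61, camera adjusted p = 0.000131). The macrophage score was lower at 24 than at 12 weeks in both genotypes, -0.97 against 0.34 in NeuT- and -0.35 against 0.22 in NeuT+. Of 19 neutrophil genes 7 rose (9; median 0.21, adjusted p = 0.000131) and of 9 promyelocyte genes 3 rose (5; median 0.24, adjusted p = 0.00149), these 3 lists each having adjusted p = 0.234 with an estimated correlation. The complement genes C1qb and C1qa were higher in NeuT+ by 1.04 ± 0.255 and 0.95 ± 0.244 and Ifitm6 by 0.74 ± 0.200. Mmp9, the gelatinase of neutrophil granules, rose by 0.41 ± 0.0852 and Cebpe, a transcription factor of granule formation, by 0.34 ± 0.0954. Of 17 myeloid suppressor genes 6 rose (8 adjusted over the list alone; median 0.29, adjusted p = 0.000131, and adjusted p = 0.128 with an estimated correlation). Clec4e stood at 0.87 ± 0.193 and Ncf1 at 0.55 ± 0.126. Of 24 interferon response genes 9 rose (11 higher and 1 lower adjusted over the list alone; median 0.34, adjusted p = 2.34e-05, and adjusted p = 0.234 with an estimated correlation). Rtp4 stood at 1.32 ± 0.219 and Isg15 at 1.09 ± 0.220. Of 20 inflammatory genes 4 rose (4 adjusted over the list alone; median 0.25, adjusted p = 0.0164, and adjusted p = 0.345 with an estimated correlation). Il1r2 rose by 1.23 ± 0.226 and Socs3, a feedback inhibitor of cytokine signalling, by 1.00 ± 0.307. Of 13 megakaryocyte genes 1 rose, Selp by 0.81 ± 0.220 (1 adjusted over the list alone; median 0.27, adjusted p = 0.0247, and adjusted p = 0.442 with an estimated correlation). Of 24 cell cycle genes 5 fell (5 adjusted over the list alone; median -0.15, adjusted p = 0.00775, and adjusted p = 0.282 with an estimated correlation). Mcm2 fell by 0.31 ± 0.0945. Within series 12 and 13 the score differences were -1.65 and -0.41 for erythroid genes, 0.58 and 0.16 for neutrophil genes and 0.71 and 0.34 for interferon genes. They were -0.64 and 0.96 for macrophage and -0.11 and 0.42 for megakaryocyte genes, opposite in direction between the series. Without NeuT- replicate 1 the medians were -0.42 for erythroid, 1.16 for macrophage, 0.14 for myeloid suppressor and 0.46 for megakaryocyte genes. Leaving out NeuT+ replicate 3 gave 0.39 for macrophage genes, leaving out replicate 5 gave 0.32 for neutrophil genes and leaving out replicate 2 gave 0.40 for megakaryocyte genes. With the deposited and the log2 quantile values the macrophage median was 0.33 and 0.31. The megakaryocyte list was lost without NeuT+ replicate 1, 3 or 4 or NeuT- replicate 2 or 5 (adjusted p from 0.0516 to 0.0821; over all alternatives 0.000237 to 0.442). The inflammatory list was lost without NeuT+ replicate 4 (0.0715), without a block and with the osteoblast score (over all 0.00184 to 0.345). The cell cycle list was lost without NeuT- replicate 1 (0.0667), with series 13 alone and with median scaling (over all 0.00146 to 0.282).

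The remaining 11 lists were not called at 24 weeks. Of 13 stem and progenitor genes 4 fell and 2 rose (5 and 2 adjusted over the list alone; median -0.26, adjusted p = 0.0519). Sox4 stood at -1.41 ± 0.210, Mllt3 at -0.77 ± 0.186 and Kit, the receptor of stem cell factor, at -0.31 ± 0.0945. The stem cell list was called with the deposited, the log2 quantile and the median-scaled values and without NeuT+ replicate 1, 3 or 5 or NeuT- replicate 2 or 3 (adjusted p from 0.0152 to 0.0440; over all alternatives 0.0152 to 0.305). Of 20 stroma genes 5 fell (6 adjusted over the list alone; median -0.19, adjusted p = 0.108). Sparc fell by 1.12 ± 0.374 and Thy1 by 0.48 ± 0.149. Of 7 osteoblast genes 2 fell, Bglap and Bglap2, and 1 rose (3 and 1 adjusted over the list alone; median -0.17, mean -0.78, adjusted p = 0.159). The latter, Mepe, was detected in 1 of 6 NeuT+ and 0 of 5 NeuT- mice, so no fold is given. Of 12 eosinophil, basophil and mast cell genes Hdc, the histamine-forming enzyme, rose by 0.67 ± 0.114 and Prg2, a granule protein of eosinophils, fell by 0.61 ± 0.163 (1 and 1 adjusted over the list alone; median -0.31, adjusted p = 0.318). Of 12 monocyte genes 2 rose, Cd14 by 0.64 ± 0.200 and Fcgr3 by 0.29 ± 0.104 (2 adjusted over the list alone; median 0.07, adjusted p = 0.393). Scd1 was the 1 of 6 adipocyte genes that fell, by 1.56 ± 0.316 (2 adjusted over the list alone; median -0.23, adjusted p = 0.386). Pecam1 was the 1 of 12 endothelial genes that fell, by 0.46 ± 0.142 (1; median -0.16, adjusted p = 0.662). Dnajb1 was the 1 of 18 immediate early genes that fell, by 0.26 ± 0.0916 (0; median -0.27, adjusted p = 0.379). Of 5 osteoclast genes 1 rose, Mmp9 (1 adjusted over the list alone), and the median was -0.11 and the mean -0.04 while the test pointed upward (adjusted p = 0.488). Of 7 skeletal muscle genes 0 passed (median -0.22, adjusted p = 0.449), and of 9 mammary epithelium genes 0 passed (median 0.01, adjusted p = 0.386), both also 0 adjusted over the list alone. The stroma and immediate early lists were also past the threshold in some alternative (camera adjusted p over all alternatives 0.0476 to 0.930 and 0.0471 to 0.963). Fry called 13 of the 25 lists at this age.

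**Figure D2:**
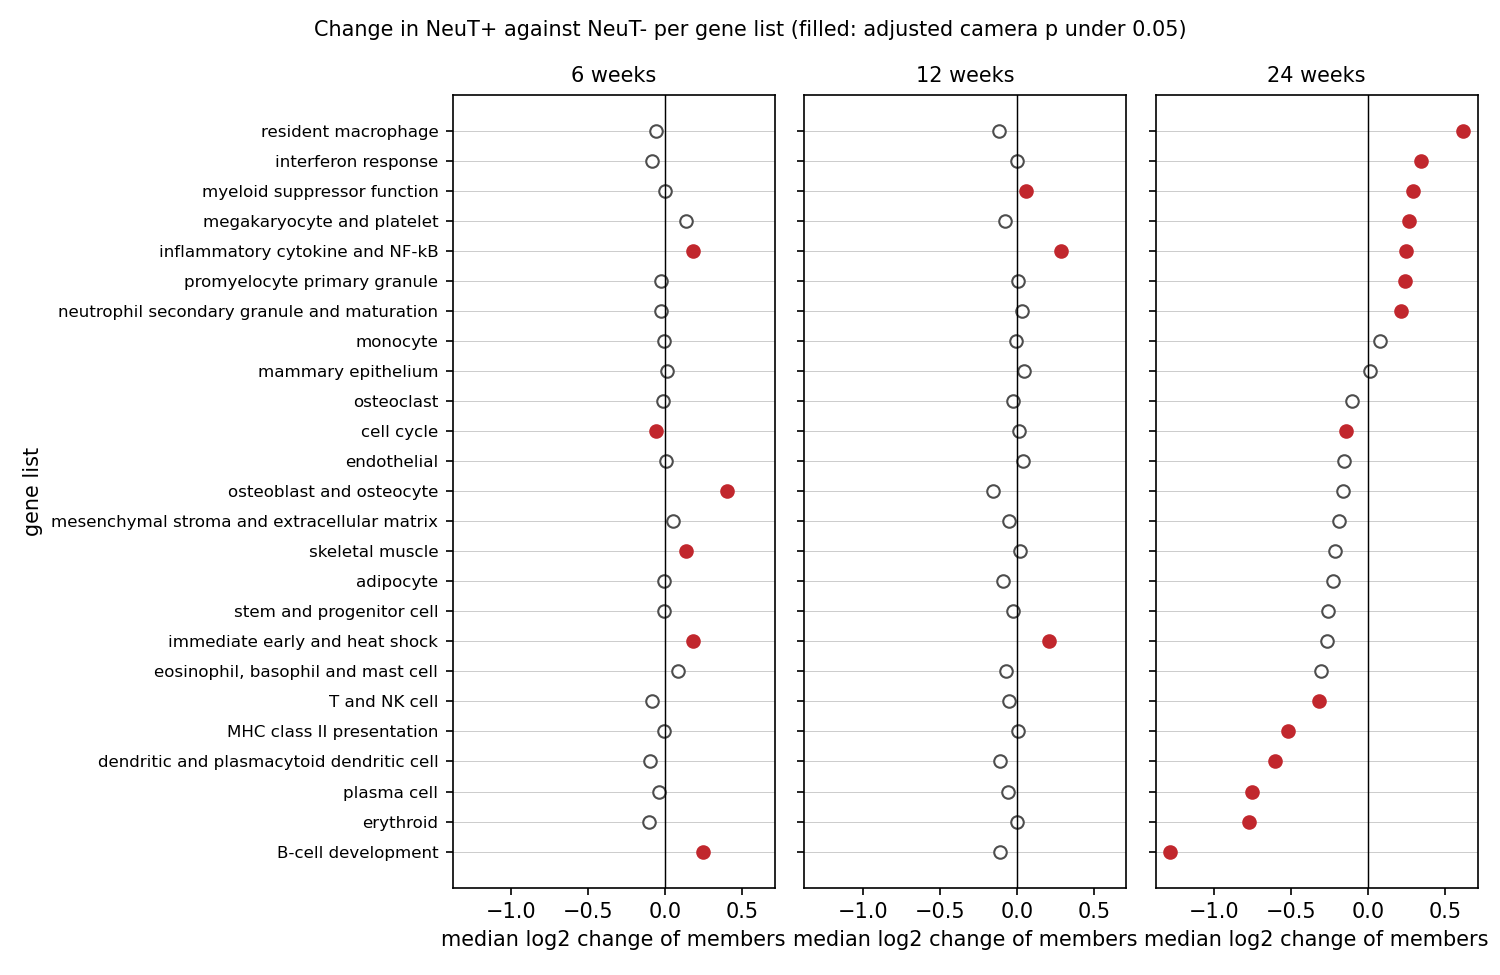
Median log2 change, NeuT+ against NeuT-, of each of the 25 gene lists at 6, 12 and 24 weeks; filled points mark lists with a camera adjusted p under 0.05. The medians at 24 weeks run from -1.28 for B-cell development to 0.61 for resident macrophages, with 6, 3 and 14 lists called at the 3 ages.

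Whether the genotype effect itself differed between ages was tested as a difference of differences. From 12 to 24 weeks the effect on 363 genes changed, 96 upward and 267 downward, and from 6 to 24 weeks that on 1116, 487 upward and 629 downward. From 6 to 12 weeks limma called 0 genes, with 600 at an unadjusted p under 0.05. Among the 0 called, Dph2 (-0.40 ± 0.0949), Eva1b (-0.52 ± 0.127) and H2ac8 (-0.86 ± 0.216) had among the smallest p (adjusted p of at most 0.595). From 6 to 24 weeks the effect on Mcam rose by 2.38 ± 0.412 log2 units (SE, adjusted p = 0.000265), on Prok2 by 2.31 ± 0.511, on Upp1 by 2.00 ± 0.322, on Acod1 by 1.99 ± 0.353 and on Tgm1 by 1.85 ± 0.375. That on Bglap changed by -2.97 ± 0.668, on Bglap2 by -2.95 ± 0.665, on Col1a1 by -2.78 ± 0.707, on Reln by -2.28 ± 0.382 and on 4930426D05Rik by -2.22 ± 0.377. From 12 to 24 weeks the effect on the interferon-induced genes Oasl2 and Rtp4 rose by 1.51 ± 0.413 and 1.27 ± 0.277, and on Fam20c, Pdzk1 and Upp1 by 1.42 ± 0.327, 1.36 ± 0.365 and 1.28 ± 0.323. The effect on Cplx2 changed by -1.72 ± 0.334, on Chst3 by -1.63 ± 0.365, on Irf4 by -1.63 ± 0.327 and on Lgr5 by -1.62 ± 0.352, and that on Peg3 was smaller at 24 weeks (limma adjusted p = 0.000249). The NeuT+ level of Peg3 at 24 weeks was 11.53 in series 12 and 9.87 in series 13, so its smaller effect cannot be told apart from series. B-cell development genes shifted downward from 6 to 24 weeks (15 of 16 members, 15 adjusted over the list alone; median -1.55, adjusted p = 1.25e-17, and adjusted p = 0.0490 with an estimated correlation). Over these ages Ms4a1 shifted by -1.66 ± 0.269 and Ebf1, a transcription factor of early B cells, by -1.46 ± 0.248. The list also shifted downward from 12 to 24 weeks (12 of 16, 15 adjusted over the list alone; median -1.19, adjusted p = 2.46e-16, and adjusted p = 0.0666 with an estimated correlation). The genotype effect on plasma cell genes shifted downward from 6 to 24 weeks (4 of 9, with 6 lower and 1 higher adjusted over the list alone, median -0.67, camera adjusted p = 0.00775, and adjusted p = 0.0490 with an estimated correlation). It did so too from 12 to 24 weeks (4 of 9, with 5 and 1, median -0.75, camera adjusted p = 0.00286, and adjusted p = 0.0438 with an estimated correlation). Mzb1 shifted by -1.20 ± 0.203 and -0.94 ± 0.204. Interferon genes shifted upward from 6 to 24 weeks (8 of 24, 11 adjusted over the list alone; median 0.44, adjusted p = 3.59e-06, and adjusted p = 0.196 with an estimated correlation). Isg15 shifted by 1.16 ± 0.277.

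Camera called 6 lists from 6 to 12 weeks (4 upward and 2 downward, of which 0 held with an estimated correlation and fry called 0), 13 from 12 to 24 weeks (6 and 7) and 11 from 6 to 24 weeks (5 and 6). From 6 to 12 weeks the B-cell median changed by -0.28 (adjusted p = 0.00226, and adjusted p = 0.925 with an estimated correlation) and the osteoblast median by -0.52 (adjusted p = 0.00201, and adjusted p = 0.333 with an estimated correlation). From 12 to 24 weeks macrophage genes shifted by 0.73 (1 of 12, 6 adjusted over the list alone; adjusted p = 7.49e-06) and erythroid genes by -0.77 (1 of 22, 16 adjusted over the list alone; adjusted p = 7.72e-11), both having adjusted p = 0.196 with an estimated correlation. C1qb shifted by 1.14 ± 0.323 and Ermap by -0.96 ± 0.274. The 12 to 24 week difference was also reached by chance regroupings of the mice, up to 725 genes. The count was 40 without NeuT- 24-week replicate 1, 208, 188 and 700 without NeuT- replicates 2, 3 and 4, and 178, 240, 762 and 193 without NeuT+ replicates 2, 4, 5 and 6. It was 183 with median scaling (10.4% higher against 26.4% here), 224 without a detection filter, 83 with the compared groups alone, 125 without a block and 51 with series 13 alone. Of the genes named for it all but Pdzk1 and Peg3 were lost without NeuT- replicate 1. The 6 to 24 week count was 264 without that mouse, 546 without a block, 439 without series 17 and 309 with series 13 alone. With median scaling 17.2% of 835 calls were higher against 43.6% here and the median of all genes moved by -0.12. Bglap, Bglap2 and Col1a1 were lost without NeuT- replicate 1 and with series 13 alone.

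**Figure D3:**
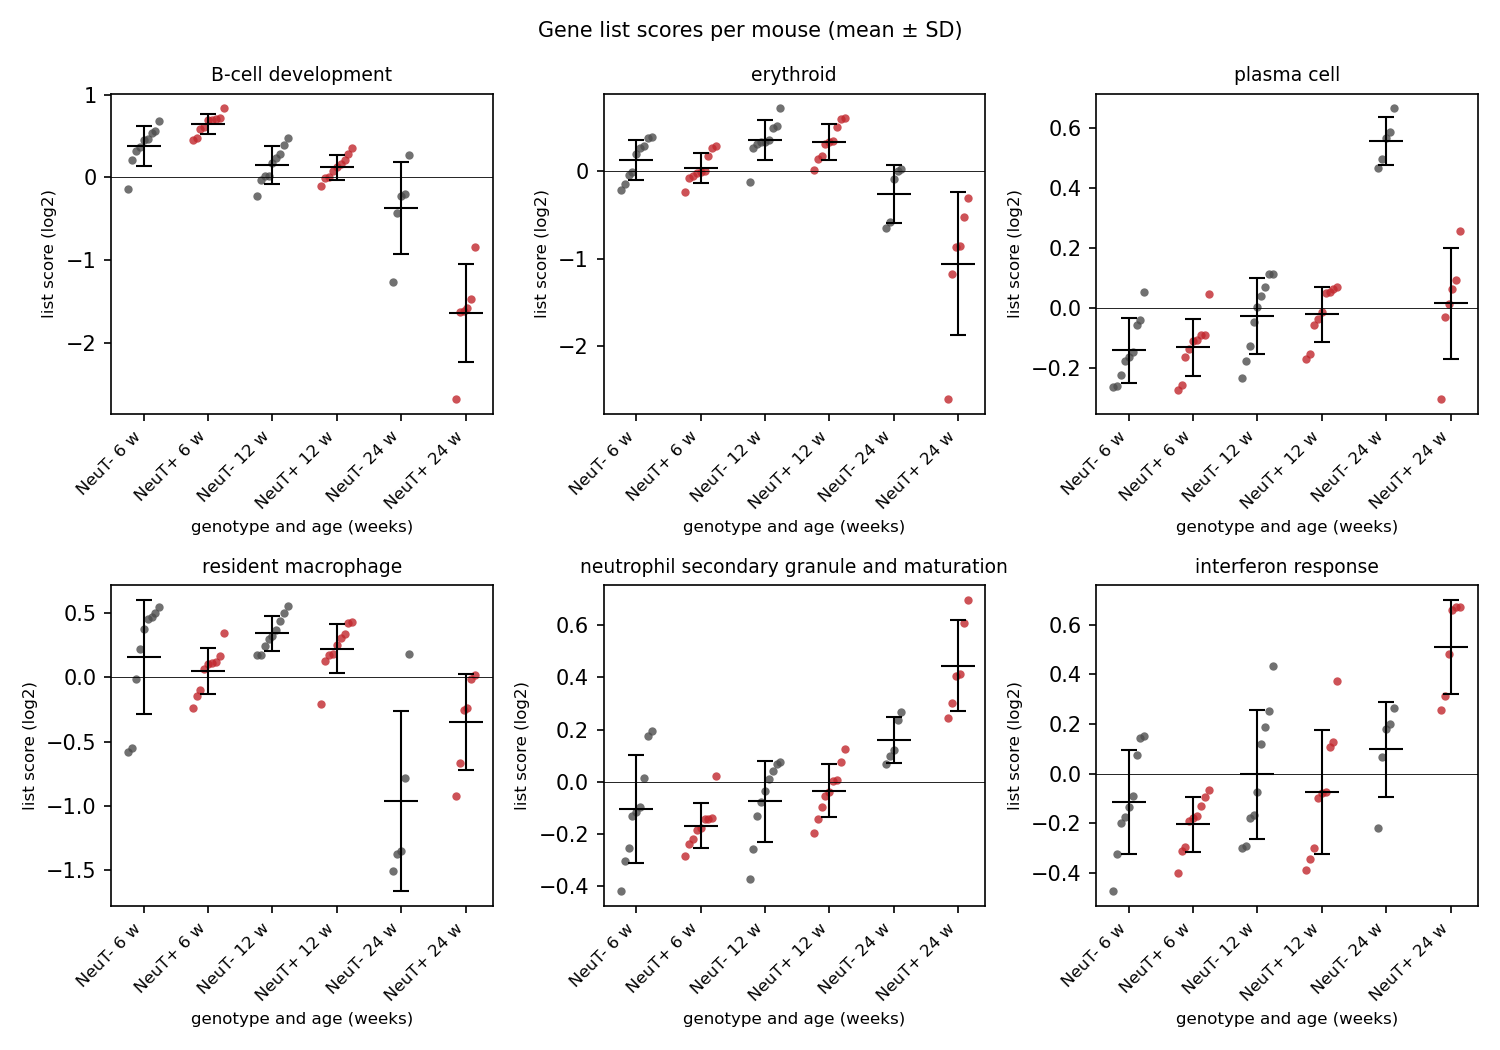
Score of 6 gene lists in each mouse (points; mean log2 value of the measured members, centred on the mean over mice) by age in weeks and genotype, with group mean and SD as bars. The B-cell score was -0.37 in NeuT- and -1.64 in NeuT+ mice at 24 weeks, and the macrophage score fell from 12 to 24 weeks in both genotypes, to -0.97 and -0.35.

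Ages were compared within each genotype to describe how the marrow changed as the mice grew older. From 6 to 12 weeks in NeuT- mice 27 genes passed, 13 higher and 14 lower. With median scaling 39 passed and 71.8% were higher against 48.1% here. Ighg1, an immunoglobulin heavy chain gene, rose 4.65-fold (log2 fold change 2.22 ± 0.267 SE, n = 9 and 9, adjusted p = 1.5e-06), and the immediate early gene Egr2 by 2.08 ± 0.393. Ifng, which encodes interferon gamma, rose by 1.15 ± 0.221 and G0s2 by 1.06 ± 0.216, and the chemokine gene Ccl2 was at least 1.58-fold higher. Igf2bp3, an RNA-binding protein of fetal tissues, fell by 1.30 ± 0.210, the matrix genes Tnc and Col4a1 by 1.10 ± 0.254 and 1.02 ± 0.190 and the endothelial junction gene Cldn5 by 0.94 ± 0.174, and Col6a1 was at least 1.56-fold lower. Immediate early genes (1 of 18 rose, 10 adjusted over the list alone; median 0.65, adjusted p = 1.18e-14, and adjusted p = 0.00583 with an estimated correlation) and inflammatory genes (1 of 20, 6 adjusted over the list alone; median 0.27, adjusted p = 2.59e-09, and adjusted p = 0.0218 with an estimated correlation) were the 2 of 15 called lists that held. Scores of the 6-week mice of series 17 lay apart: the immediate early score was -0.97 in NeuT+ and -1.09 in NeuT- mice of that series, against -0.30 to -0.01 in series 12 and 14, and the inflammatory score -0.80 and -0.84, against -0.41 to 0.02. Without series 17 the medians in NeuT- were 0.45 and 0.28 (adjusted p = 1.73e-07 and adjusted p = 0.000192), and neither call held with an estimated correlation (adjusted p = 0.0685 and adjusted p = 0.145). In NeuT+ mice 635 genes passed over the same ages, 236 higher and 399 lower. Ighg1 rose 9.12-fold (3.19 ± 0.267) and the stress-induced factor gene Atf3 8.37-fold (3.06 ± 0.564), with Egr2 at 2.12 ± 0.393, Trem1 at 1.82 ± 0.246 and Ccl2 at 1.81 ± 0.330. Igf2bp3 fell by 1.72 ± 0.210, Col1a1 by 1.62 ± 0.488, Bglap by 1.49 ± 0.437 and Sparc by 1.46 ± 0.317, and Tnc was at least 1.70-fold lower. Inflammatory (7 of 20 rose, 9 adjusted over the list alone; median 0.52, adjusted p = 4.66e-10) and immediate early genes (7 of 18, 12; median 0.78, adjusted p = 9.28e-10) again held with an estimated correlation (adjusted p = 0.0253 and adjusted p = 0.0302). Without series 17 their medians were 0.26 and 0.41 (adjusted p = 2.76e-05 and adjusted p = 3.76e-06), and neither held with an estimated correlation (adjusted p = 0.114 for both). Stroma genes fell (10 of 20, 11 lower and 1 higher adjusted over the list alone; median -0.54, adjusted p = 1.72e-06, and adjusted p = 0.0847 with an estimated correlation). Bgn fell by 1.12 ± 0.168. All 27 genes called in NeuT- were also called in NeuT+ in the same direction, 13 higher and 14 lower (0.271 and 0.494 by chance if independent). The genotypes of an age came from the same number series, so these lists are not independent. With series 12 alone the counts were 11 in NeuT- (1 of them among the 27) and 12 in NeuT+, and with a random block 5 and 79. In NeuT+ 329 passed with median scaling and 201 without series 17. With series 12 alone all genes named for NeuT- but Ccl2, and Atf3, Egr2, Trem1, Ccl2, Tnc, Col1a1, Bglap and Sparc for NeuT+, were lost. With a random block Ccl2, Ifng, G0s2, Col6a1, Tnc, Col4a1 and Cldn5 were lost in NeuT- and Col1a1, Bglap and Sparc in NeuT+. Without series 17 Ccl2, Ifng and G0s2 were lost in NeuT- and again Col1a1, Bglap and Sparc in NeuT+. In NeuT- the deposited and the log2 quantile values also lost Ccl2 and Tnc, a fit without a detection filter Tnc, and a fit of the compared groups alone Igf2bp3 and Cldn5. In NeuT+ Col1a1 and Bglap were also lost without a detection filter and with the compared groups alone.

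From 12 to 24 weeks in NeuT- mice 482 genes passed, 280 higher and 202 lower. With median scaling 129 passed and 24.8% were higher against 58.1% here. Ighg1 rose 5.44-fold (log2 fold change 2.44 ± 0.316 SE, n = 5 and 9), Ces1d by 2.04 ± 0.263 and Jchain by 1.80 ± 0.184, and the plasma cell genes Tnfrsf17 and Derl3 were at least 2.18-fold and 1.70-fold higher. The macrophage genes Spic, Axl and C1qb fell by 1.92 ± 0.296, 1.80 ± 0.242 and 1.80 ± 0.240, the lectin gene Fcna by 1.93 ± 0.282 and Bglap2 by 1.81 ± 0.531. Resident macrophage genes fell (9 of 12, 11 adjusted over the list alone; median -1.61, adjusted p = 6.82e-21, and adjusted p = 0.00520 with an estimated correlation) and plasma cell genes rose (3 of 9, with 6 higher and 1 lower adjusted over the list alone; median 0.22, adjusted p = 1.46e-06, and adjusted p = 0.00115 with an estimated correlation), the 2 of 10 called lists that held. In series 12, which alone held both ages, the NeuT- macrophage score was 0.33 at 12 weeks and 0.18 in its 1 mouse at 24 weeks. The score was -1.25 in series 13, which held 24-week mice alone, so the macrophage fall cannot be told apart from series. For plasma cell genes the series 12 scores were 0.06 and 0.59. Erythroid genes fell in NeuT- too (7 of 22, 14 adjusted over the list alone, median -0.56, camera adjusted p = 4.82e-11, and adjusted p = 0.181 with an estimated correlation). In NeuT+ mice 4602 genes passed (40.7%), 2248 higher and 2354 lower. With median scaling 37.7% of 3498 were higher against 48.8% here. Cxcr1, a chemokine receptor of neutrophils, rose 5.75-fold (2.52 ± 0.363, n = 6 and 9), Prok2 by 2.50 ± 0.355, Wfdc17 by 2.47 ± 0.356 and Upp1 by 2.36 ± 0.256, and Ambp was at least 2.36-fold higher. Bglap2 fell 12.5-fold (-3.65 ± 0.502), and the fold changes of Bglap, Cplx2, Col1a1 and Lgr5, a receptor for R-spondins, were -3.53 ± 0.489, -3.10 ± 0.414, -2.73 ± 0.545 and -2.46 ± 0.288 on the log2 scale. All 16 B-cell genes fell (16 adjusted over the list alone; median -1.78, adjusted p = 5.00e-16, and adjusted p = 0.0843 with an estimated correlation). Of 22 erythroid genes 21 fell (22 adjusted over the list alone; median -1.43, adjusted p = 2.22e-15, and adjusted p = 0.113 with an estimated correlation). Cell cycle genes fell too, 17 of 24 (17 adjusted over the list alone; median -0.32, adjusted p = 1.35e-05, and adjusted p = 0.113 with an estimated correlation). Of 9 promyelocyte genes 8 rose (8 adjusted over the list alone; median 0.56, adjusted p = 1.35e-05, and adjusted p = 0.113 with an estimated correlation). Ctsg rose by 0.74 ± 0.0981. Macrophage genes fell in NeuT+ as well (8 of 12, 9 adjusted over the list alone; median -0.63, adjusted p = 0.0191, and adjusted p = 0.457 with an estimated correlation). Of the NeuT- calls 258 of 280 higher and 173 of 202 lower were shared with NeuT+ (55.7 and 42.0 by chance if independent, which lists from the same series are not). In NeuT- mice the count was 1472 without 24-week replicate 1, 72 without replicate 4 or 5 and 185 without replicate 3. It was 27 with a random block, 1719 with series 13 alone and 0 with series 12 alone (limma, 917 at an unadjusted p under 0.05). With series 12 alone all the genes named for NeuT- were lost and Fcna turned to 0.13, and series 12 held a single 24-week NeuT- mouse, replicate 1, whose age label is uncertain. Bglap2 was lost in 7 of 23 alternatives, which included median scaling, no detection filter, a random block and leaving out replicate 3, 4 or 5.

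Log10 of tumor burden was set against the list scores of the 6 NeuT+ mice with burden at 12 weeks, from 39293 to 798790 in a unit the labels do not give, and of the 6 at 24 weeks, from 20296073 to 156499187. Neutrophil genes had the smallest p at 12 weeks (Pearson r = -0.931, exact permutation p = 0.00278, adjusted p over 25 lists 0.0695). Spearman's rho was -0.943 (exact p = 0.0167), and r was -0.954 without the 2 mice farthest from the median burden (exact p = 0.0833). In all 0 lists passed by exact permutation, with 4 at an unadjusted p under 0.05. At 24 weeks MHC class II genes had the smallest p (r = -0.864, exact permutation p = 0.025, adjusted p 0.556; rho = -0.771, exact p = 0.103), with r = -0.750 without the 2 farthest mice. Again 0 lists passed by exact permutation, with 1 at an unadjusted p under 0.05. The smallest two-sided p that 6 mice allow is 0.00139. The number series held at most 4 of these mice each. No relation was computed within a series, so burden is not separated from series here.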

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

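Among the tests in this part, those of normalization and of mammary cells for Peg3, those of bone share, number series and myeloid dilution for B-cell genes and those of death to lysis and array signal for inflammatory genes were chosen only after the results were seen.

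Peg3 was far higher in NeuT+ marrow at all 3 ages. Background correction and normalization are excluded as its cause by the raw signals, in which 24 of 24 NeuT+ mice lay above each NeuT- mouse. Mammary epithelial or tumor cells in the marrow were examined with the mammary list at 6 weeks, the only age tested. Its mean log2 change was -0.00286 (SE 0.0307). Krt8, Krt19, Csn3, Cldn3, Krt14 and Muc1 were detected in 0 of 47 mice, so most of the list lay below background. This argues against a share of such cells large enough to raise these genes above background at 6 weeks. A smaller share, or one at the later ages, is not covered. A change over the wider chromosome region is argued against by the 20 measured genes nearest to Peg3, whose median change averaged over the ages was -0.0335 (SD 0.0974). Usp29 and Zim1, genes of the Peg3 region, were detected on no array and could not enter, so a change confined to the closest genes is not covered. An effect of the transgene or of its insertion site on Peg3 may be at work and stays open, since no test here could separate it from the genotype.

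B-cell development genes were lower in NeuT+ marrow at 24 weeks by camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.0751). A difference in the share of bone is argued against as the whole cause, because the median of the list was -1.25 with the osteoblast score as covariate and -1.28 without it (adjusted p = 9.29e-15 with it). A larger share of myeloid cells diluting all other cells alike was examined with the megakaryocyte list, whose mean change exceeded that of the B-cell list by 1.53 (SE 0.229). This does not decide it, because megakaryocytes are not plainly outside the myeloid branch. Their score difference was also -0.11 in series 12 and 0.42 in series 13. The median change of T and NK cell genes was -0.32, against -1.28 for B-cell genes, and this difference was not tested. The number series is argued against as the whole cause by a score difference of -1.24 with the series as a block (exact permutation within series, p = 0.0143) against -1.27 without it, though within series 13 alone the difference was -0.847 (exact permutation p = 0.0571, 4 against 4 mice). A fall in B-cell production or numbers in tumor-bearing mice is a candidate explanation that was not tested.

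Inflammatory cytokine and NF-kB genes were shifted upward in NeuT+ marrow at 12 weeks (adjusted p = 0.0442 with an estimated correlation). Time between death and lysis, read from immediate early genes, is argued against as the whole cause by a median of 0.233 with that score as covariate against 0.285 without it (adjusted p = 9.52e-07 with it). The median raw signal of the arrays was 128.5 ± 18.1 in NeuT+ and 131.2 ± 20.1 in NeuT- mice of this age (SD, n = 9 and 9). With it as covariate the list's median was 0.298 (camera adjusted p = 2.18e-10), but this covariate changed no list call at any age. The like signals argue against array strength only as far as the median raw signal records it. An inflammatory response to early lesions may be at work, as may handling that immediate early genes do not record, and neither was tested.

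Chance regroupings of the mice, 100 per comparison with the real one included, were counted for each number of called genes. At 6 weeks 4 of them gave at least the real 1 gene (highest other 1), so a count of 1 was also reached by other regroupings. At 12 weeks 1 gave at least 17 (highest other 7), and at 24 weeks 1 gave at least 1954, so regroupings of the mice do not account for the counts at 12 and 24 weeks. The highest other at 24 weeks, 1701, kept 1 of 11 mice in its group and is close to the mirror image of the real split. At that age 32 of the other regroupings called some gene (median count 0), against 5 at 12 weeks and 3 at 6 weeks. Calls at the threshold thus also came from wrong groupings, more often at 24 weeks. For the change of the genotype effect from 6 to 12 weeks all 100 gave at least the real 0 (highest other 1). From 12 to 24 weeks 5 gave at least the real 363, with 725 in the highest other, so chance cannot be excluded. From 6 to 24 weeks 2 gave at least 1116. The highest other, 1287, exceeded the real count and kept 17 of 29 mice in their groups, so chance is made less likely but is not excluded. In NeuT- mice 3 gave at least the real 27 genes from 6 to 12 weeks (highest other 40) and 1 gave at least 482 from 12 to 24 weeks (highest other 3). In NeuT+ mice 1 gave at least 635 (highest other 32) and 1 gave at least 4602 (highest other 1672, which kept 3 of 15 mice in their groups). Chance regroupings of single mice do not account for the counts 482, 635 and 4602, but the count of 27 was exceeded by the highest other. Such regroupings ignore the number series, of which series 12 alone spans ages, so chance differences between series are not excluded: with a random block the counts 27, 482, 635 and 4602 were 5, 27, 79 and 3084.

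The genotype effect differed between ages by its own test for 363 genes and 13 lists from 12 to 24 weeks, for 1116 genes and 11 lists from 6 to 24 weeks and for 6 lists from 6 to 12 weeks. With an estimated correlation 1, 2 and 0 of these lists were called, and fry called 11, 12 and 0 lists. Chance is not excluded for the 363 genes or for the 1116. Reference RNA enters no comparison of mice, though its arrays shared the quantile normalization and the detection filter with theirs. It exceeded each mouse array by over 3 log2 units in 375 genes.

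Single mice lay far from the rest of their group, measured as the gap to the nearest mouse over the range of the group. Chance flags about 1 in 20 groups: of 232 groups tested 22 met this, against 11.6 by chance. For array signal these were the median raw signal of NeuT- 24-week replicate 5 (155.0 against 127.4 in the nearest, gap 0.771) and of reference replicate 2 (147.5 against 112.3, gap 0.846) and the detected probes of NeuT+ 24-week replicate 1 (15818 against 15007, gap 0.654). For list scores in the 24-week groups they were, in NeuT- replicate 1, stem and progenitor genes (0.13, gap 0.711) and mammary genes (-0.13, gap 0.779), in NeuT+ replicate 1, megakaryocyte genes (0.81, gap 0.632), and in NeuT+ replicate 2, eosinophil (-1.48, gap 0.668), endothelial (-0.58, gap 0.671) and myeloid suppressor genes (0.99, gap 0.715). At 12 weeks they were macrophage genes in NeuT+ replicate 3 (-0.21, gap 0.525) and mammary genes in NeuT+ replicate 2 (0.21, gap 0.609). At 6 weeks they were T and NK cell genes (-0.49, gap 0.542) and muscle genes (-0.42, gap 0.519) in NeuT- replicate 4, osteoclast genes in NeuT- replicate 2 (-0.54, gap 0.535), neutrophil genes in NeuT+ replicate 9 (0.02, gap 0.530) and adipocyte genes in NeuT+ replicate 1 (0.07, gap 0.586). For named genes they were Peg3 in NeuT- 12-week replicate 2 (6.74 against 5.96, gap 0.534), Tnfaip3 in NeuT- 12-week replicate 6 (10.92, gap 0.609) and NeuT+ 12-week replicate 7 (11.88, gap 0.537), H2ac8 in NeuT- 12-week replicate 1 (10.37, gap 0.550), Ambp in NeuT+ 24-week replicate 2 (9.54, gap 0.634) and Col1a1 in NeuT+ 24-week replicate 3 (7.83, gap 0.719).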

How the results depend on the processing

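Leaving out each 6-week or 12-week mouse, each mouse for gene lists, series 17, or all 24-week mice but series 13, the covariates, and median scaling of the lists were chosen after seeing the data. No paired analysis was possible because replicate numbers were given in accession order and pair no mice. Of the named genes, those at 24 weeks stayed past the threshold in the same direction in 471 of 500 values under alternatives and those at 12 weeks in 267 of 402, and in the comparison of 24 with 12 weeks in NeuT+ in 230 of 230. Array signal over background limits genes near the detection limit. The number of calls stayed within 1.5 times of its value in 27 of 32 alternatives at 6 weeks, 12 of 31 at 12 weeks, 19 of 25 at 24 weeks, 10 of 23 for the 12 to 24 week difference and 20 of 24 for the 6 to 24 week difference, and in 23 of 23 for 24 against 12 weeks in NeuT+. The cause was not tested for any move below except where fewer mice entered the fit.

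At 6 weeks the count of 1 gene was 2 with a random block and 2 with the osteoblast score, and ran from 1 to 2 over left-out mice. At 12 weeks the count of 17 was 32 with the deposited values, 31 with log2 quantile values, 33 with the mean of probes, 26 with the compared groups alone, 2 without a block, 10 with the osteoblast score and 5 with the immediate early score, and ran from 2 to 41 over left-out mice. At 24 weeks the count of 1954 was 278 with the compared groups alone, 1259 without a block, 1160 with the osteoblast score and 431 with series 13 alone, and ran from 341 to 2360. The 12 to 24 week difference in 363 genes was 183 with median scaling, 224 without a detection filter, 83 with the compared groups alone, 125 without a block and 51 with series 13 alone, and ran from 40 to 762. The 6 to 24 week difference in 1116 genes was 546 without a block, 439 without series 17 and 309 with series 13 alone, and ran from 264 to 1499.

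From 6 to 12 weeks the count of 27 in NeuT- was 5 with a random block and 11 with series 12 alone, and that of 635 in NeuT+ was 329 with median scaling, 79 with a random block, 12 with series 12 alone and 201 without series 17. From 12 to 24 weeks the count of 482 in NeuT- was 129 with median scaling, 27 with a random block, 0 with series 12 alone (limma, 917 at an unadjusted p under 0.05) and 1719 with series 13 alone, and ran from 72 to 1472 over left-out mice, and that of 4602 in NeuT+ ran from 4030 to 4624. Fcna, lower in NeuT- at 24 weeks, turned to 0.13 with series 12 alone.

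With an estimated correlation 0 lists were called at 6 weeks, 1 at 12 weeks and 1 at 24 weeks. At 12 weeks 1 list was called without a block, 1 with the osteoblast score and 1 with the immediate early score. Over left-out mice the number of lists ran from 4 to 10 at 6 weeks, 2 to 3 at 12 weeks and 12 to 15 at 24 weeks. The skeletal muscle median at 6 weeks turned to -0.081 without series 17. With the deposited values 0 lists were related to tumor burden (exact permutation). Leaving out the 2 mice farthest from the median burden also gave 0. The few mice then left allow too few pairings for a list to pass readily, so that 0 says little (smallest exact p at 12 weeks 0.0833). The spread between mice over that between reference arrays was 2.41 and with the deposited values 2.36.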

Other observations

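The genes and measures of this part were chosen after the values were seen, and no explanation of them was tested.

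Some genes differed between genotypes in the same direction at all 3 ages. Apart from Peg3, 3 genes had an unadjusted p under 0.01 in one direction at each age (limma): Cd160, a receptor of NK and T cells, with log2 fold changes of 0.39, 0.50 and 0.62 at 6, 12 and 24 weeks, Klk1b5 with -0.66, -0.40 and -1.36, and Zg16, a secreted lectin, with -0.45, -0.38 and -0.73. With Peg3 these were 4 of 11309 genes, where 0.218 would be expected if ages were independent, from the number past that p at each age. In the genotype effect averaged over the ages 972 genes passed, 302 higher and 670 lower. This average weights the 3 ages alike and can be carried by a single age. At 6, 12 and 24 weeks 1, 17 and 1954 genes passed, so 972 is not a count of genes that differed at each age. Kallikrein genes stood near the top: Klk1b5 fell by 0.81 ± 0.0906 (SE), Klk1 by 0.81 ± 0.110, Klk1b26 by 0.75 ± 0.109 and Klk1b27 by 0.53 ± 0.0920, while Cd160 rose by 0.50 ± 0.0626. These kallikreins are near-identical copies whose probes can bind each other's RNA, and need not be separate observations. Between the 12-week and 24-week comparisons 5 of 14 higher genes were shared, Cd160, Ets2, Nfkbib, Peg3 and Trem1, where 0.976 would be by chance, and 1 of 3 lower genes, Dph2.

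Reference RNA did not resemble marrow. The melanocyte genes Dct and Mlana stood at log2 levels of 15.42 and 13.76 on the reference arrays (n = 5) against 4.87 and 4.99 in the mice (n = 47), and the epithelial keratin gene Krt8 at 13.58 against 5.51. Mpo, the granule enzyme myeloperoxidase, stood at 4.72 against 15.91 and S100a9, an abundant neutrophil protein, at 4.72 against 15.75. Over 6862 genes detected on all arrays the median SD was 0.0855 between reference arrays, 0.207 between mice of a group and 0.175 between mice of a group and number series.

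Of 47 mice 6 lay nearest to the mean of a group of another age. NeuT- 24-week replicate 1 had the widest gap, with a correlation of 0.994 to the 12-week NeuT- mean and 0.984 to its own group, and NeuT- 6-week replicate 8 the next (0.987 to the 24-week NeuT- mean, 0.982 to its own). The others were NeuT- 6-week replicate 3, NeuT+ 6-week replicate 1 and NeuT- 12-week replicates 1 and 9. The age label of NeuT- 24-week replicate 1 is uncertain, and its scores do not all point to the same age. It was the 1 NeuT- mouse of series 12 at 24 weeks and the other 4 were of series 13, so its distance from them cannot be told apart from series. Without that mouse 341 genes passed at 24 weeks in place of 1954, and 1472 from 12 to 24 weeks in NeuT- in place of 482. The B-cell score of that mouse was 0.28 against -1.26 to -0.20 in the other 4 mice of its group, its macrophage score 0.18 against -1.51 to -0.78 and its interferon score -0.22 against 0.07 to 0.26. Its plasma cell score, 0.59, lay within theirs, 0.47 to 0.67, and outside the -0.23 to 0.115 of 12-week NeuT- mice. Also within its own group but outside the 12-week NeuT- range were its osteoblast score (-0.54 against -0.08 to 0.66) and its osteoclast score (0.17 against -0.26 to 0.07). These scores go with its 24-week label. A further 12 mice lay nearest to the other genotype of their own age, among them at 24 weeks NeuT- replicate 4 (0.994 to the NeuT+ mean against 0.993 to its own) and NeuT+ replicate 5 (0.994 to the NeuT- mean against 0.991). The labels give a dysplasia grade with a tumor burden of 0 on 6 NeuT- mice, NeuT- 12-week replicate 2 and NeuT- 6-week replicates 1 to 5, and the first of these also had the highest Peg3 of its group, 6.74, against a NeuT+ mean of 12.13.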
